A study of Rattus norvegicus with 12 samples.

How the data were processed

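Islet RNA was sequenced from 12 rat offspring in 4 groups of 3, named by the diet of the dam and the weaning diet of the pup. Groups and replicate numbers were taken from the titles of the libraries. Per the labels' protocols, islets were freed with collagenase and picked by hand, RNA was extracted with a column kit, ribosomal RNA (rRNA) was removed with Ribo-Zero and strand-specific libraries were made with the NEBNext Ultra II Directional kit. Reads were aligned with STAR 2.5.1b and counted with HOMER 4.9, per the submitters' processing notes, which also name DESeq2 without a version. Per the file headers, reads over exons were summed per gene on rat genome build rn5, on both strands and with 1 condensed entry per gene. Since both strands were counted, reads from a gene and an overlapping or antisense partner cannot be told apart. How reads that fit several places were counted is not given in the sources used here, so near-identical gene copies (ribosomal proteins, globins, trypsins, Hspa1a and Hspa1b) are uncertain as single genes.

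The deposited values are a signal scaled to library depth, per the file headers and the values themselves. The header names FPKM, but the values were not divided by gene length: in every library they are whole multiples of 1 step, the same for short and long genes. Dividing by that step gave whole reads for 100% of the values of up to 1000 reads (tolerance 0.1 of a read). The recovered gene reads came to between 11469290 and 27492858 per library, and a value of 1 stands for 1.96 to 5.02 reads. The step was taken to scale each library to HOMER's default total, which sets only the absolute size of the values and no ratio between libraries. The design had assumed FPKM, and the planned log-scale test was kept, since a signal is also tested on the log scale. edgeR and DESeq2 were run on the recovered reads as alternatives chosen after the data were seen, with rRNA entries left out. They called between 0 and 1526 genes (edgeR) and between 0 and 2277 genes (DESeq2) per contrast.

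From the deposited values, each library was divided by the median ratio to the gene-wise geometric mean over the 11337 of 17407 genes above 0 in all libraries (factors 0.83 to 1.27). These scaled values are the values printed for each group, as mean ± SD over 3 libraries. Genes with a mean scaled value of at least 1 over the 12 libraries were tested, 12339 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(scaled value + 1) with 1 mean per group over all 12 libraries. The empirical Bayes step used a mean-variance trend (median total degrees of freedom 13.37), and p-values were adjusted by Benjamini-Hochberg within each of 7 contrasts, with a threshold of 0.05. Fold changes and their standard errors (SE) are on that log2 scale, which understates changes of genes with low values. The contrasts were the weaning diet in offspring of lean dams and of GDM dams, GDM of the dam on each weaning diet, both effects averaged over the other factor, and the interaction. Where a group was at 0 in all its libraries, a fold is given as a lower bound against a floor of 3 reads in each library, which covers counting error only.

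Of 34 gene lists, 33 had at least 4 tested members, and the list of Y-linked genes and Xist (2 of 8 members tested) was left out. The lists covered islet hormones and granule peptides, beta cell identity and glucose sensing, genes usually silent in mature beta cells, beta cell dedifferentiation and progenitor genes, insulin secretion and exocytosis, alpha cell, delta and PP cell markers, the unfolded protein response, oxidative phosphorylation, fatty acid oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis, glycolysis, cytokines and NF-kB targets, the interferon response, cell cycle, apoptosis and p53 targets, antioxidant genes, hypoxia, immediate early genes, insulin and IGF signalling and the circadian clock, together with markers of the other cells that islet preparations can hold (acinar, Reg family, duct, endothelial, stellate and fibroblast, macrophage, MHC class II, T and B lymphocyte, Schwann, adipocyte and erythrocyte). Lists were tested with camera (preset correlation 0.01, two-sided), adjusted over the lists of a contrast, and beside it with an estimated correlation and with fry. A list of 77 ribosomal protein genes was chosen after the data were seen and has no adjusted list p. Mafa, G6pc2 and Insm1 matched no gene entry and were not analysed here. Some genes that the naming rule takes are not reported here. In all, 16432 reference symbols were matched by accession.

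The genes named were fixed by a rule. In each contrast they are the 12 largest rises and the 12 largest falls among genes past the threshold whose libraries did not overlap between the compared groups (a condition dropped for averaged contrasts and the interaction), leaving out provisional symbols. Where fewer than 5 genes passed, the passing genes and those of lowest p up to 10 were taken, as values and not as changes. Ins1, Ins2, Gcg, Sst, Ppy, Iapp, Pdx1, Nkx6-1, Slc2a2 and Ucn3 were always included, with up to 4 members of lowest p from each list and the most abundant members of other cells' lists. The design, the contrasts, the lists, this rule and the first set of alternatives were fixed before the data were examined.

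Single measures (rRNA share, list levels) were compared by two-sided exact permutation of the dams' or diets' labels within the other factor (400 relabellings, smallest possible p 0.005). Alternatives fixed at the start were a pseudocount of 0.1, no filter or a minimum of 5, the deposited values without rescaling, quantile normalization, the replicate number as a block, estimated library weights, the acinar level or the title letter as a covariate, only the compared groups in the fit, each library left out in turn, and the other list tests. Chosen after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0, the log2 value of Rn45s (the 45S rRNA precursor) as a covariate, removal of the trend with transcript length from each library (lowess, span 0.3), leaving out the 3 libraries with title letter K (which keeps 1 in GDM-LF) or those with over 10% rRNA reads (which keeps 7, with 1 in Lean-LF and none in Lean-HFS), a fit without the mean-variance trend, and the ribosomal protein list. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

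Each step was tested on simulated reads with known changes. At 2-fold and 4-fold changes, limma recovered 22% and 75.5% of changed genes for GDM against lean dams on LF diet (12306 genes), 26% and 77% for the same on HFS diet (12339 genes), 26% and 76% for diet in offspring of lean dams (12334 genes) and 22% and 66.3% for diet in offspring of GDM dams (12328 genes). For the averaged contrasts it recovered 50.5% and 86% for GDM (12354 genes) and 63% and 91.9% for diet (12331 genes), and for the interaction 0% and 40% (12324 genes). Unchanged genes called numbered 9, 6, 10, 4, 9, 4 and 2 in that order. Whole reads were recovered from 100% of the simulated values. With only a simulated length trend between dams (Spearman rho -0.76, 12370 genes), 1409 genes and 3 lists were called, and 0 of each after its removal.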

Results

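Pancreatic islets of rat offspring were profiled by RNA sequencing to ask how gestational diabetes mellitus (GDM) in the dam affects the islets of its offspring. Female Sprague-Dawley rats, 6 per diet, were fed either a low-fat diet (LF, 10% fat) and stayed lean or a diet high in fat and sucrose (HFS, 45% fat) that induced GDM. Feeding began 6 weeks before mating and went on to the end of suckling. Pups were weaned onto LF or HFS diet for 12 weeks and islets were taken at 15 weeks of age. This gave 4 groups of 3 libraries, Lean-LF, Lean-HFS, GDM-LF and GDM-HFS, where the first word is the dam and the second the weaning diet. The Lean-LF libraries held 18704786, 14658004 and 27492858 reads over genes and the Lean-HFS libraries 17485547, 17426884 and 13716837. The GDM-LF libraries held 13967330, 21345209 and 18248510 and the GDM-HFS libraries 24525747, 24110859 and 11469290. A letter in the title of each library, of no stated meaning, was K for GDM-LF 1, GDM-LF 2 and GDM-HFS 3 and G for all others, so the K libraries all came from offspring of GDM dams. Without them GDM-LF is the single library GDM-LF 3, assumed to vary like the other groups, and GDM-HFS has 2 libraries, so a call lost in that fit says little about the letter. Litter and sex are not given in the labels used here, so p-values measure the spread between these 12 samples.

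Hormone transcripts dominated every group. Ins1 and Ins2, the insulin genes of the rat, took 29.9 ± 1.02% of the reads outside rRNA in Lean-LF, 31.1 ± 2.23% in Lean-HFS, 28.9 ± 6.32% in GDM-LF and 32.8 ± 1.37% in GDM-HFS (SD, n = 3 each). The difference between dams did not pass (two-sided exact permutation p = 0.910). Reads of rRNA made up 14.5 ± 14.5% of gene reads in Lean-LF, 31.7 ± 7.14% in Lean-HFS, 7.97 ± 0.844% in GDM-LF and 2.91 ± 1.29% in GDM-HFS (exact permutation p = 0.0350 between dams). The length measure was each library's median log2 deviation from the gene means, for transcripts under 1000 less those over 4000 bases. It stood at -0.51 in Lean-LF, -0.20 in Lean-HFS, 0.21 in GDM-LF and 0.48 in GDM-HFS (exact permutation p = 0.00500, the smallest possible). Markers of acinar cells, the enzyme-secreting cells of the exocrine pancreas, had mean log2 levels of 8.99 ± 0.742, 9.94 ± 1.28, 10.29 ± 2.19 and 10.87 ± 0.546 in the same order (SD, n = 3). Within GDM-LF the libraries stood at 9.15, 12.8 and 8.89. The exact permutation p between dams was 0.150.

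**Figure D1:**
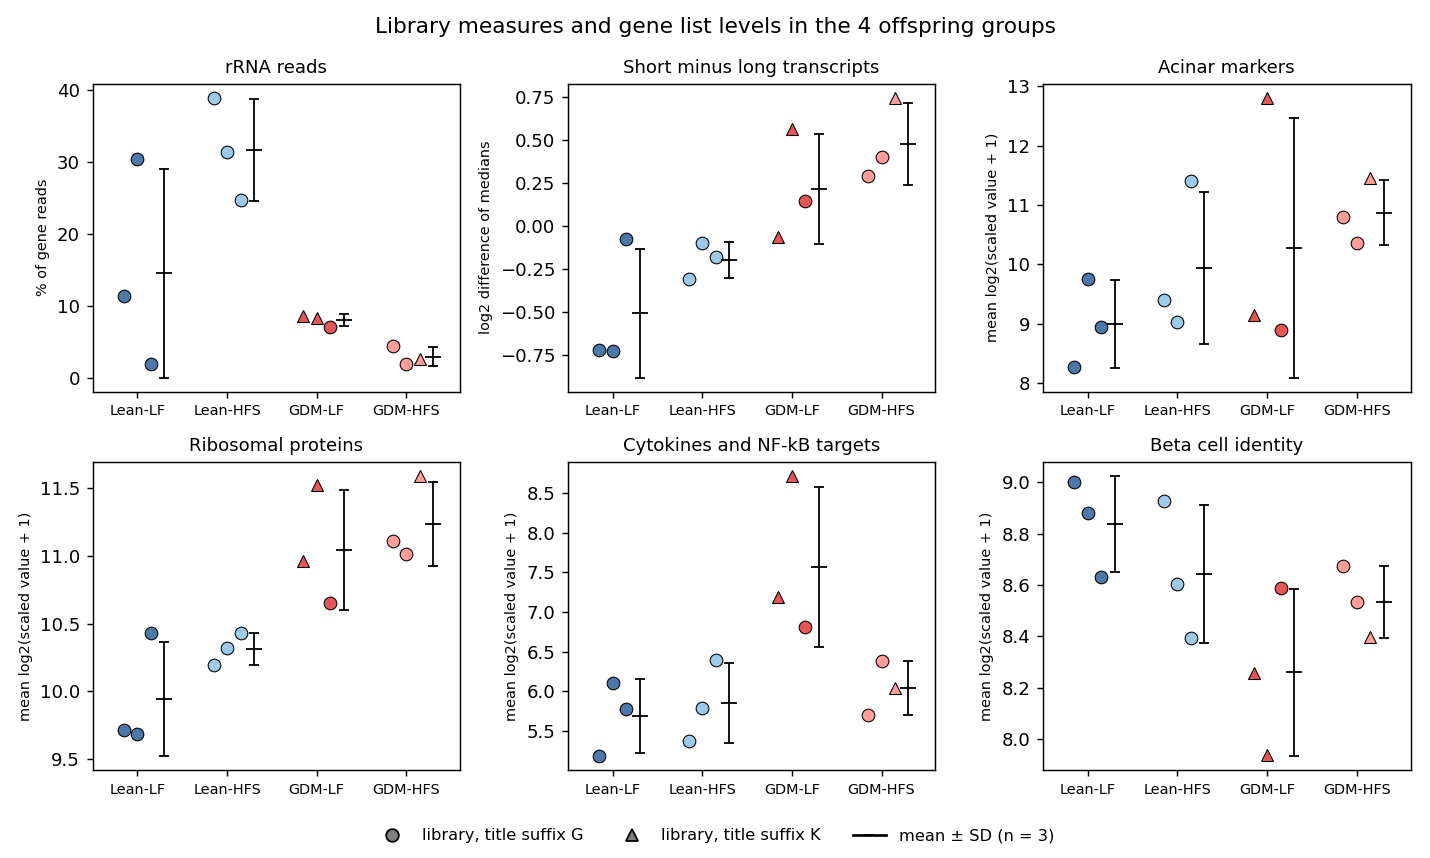
Each point is 1 library of the group on the x axis (circle, title letter G; triangle, title letter K) and the bar is the mean ± SD (n = 3); the 6 panels plot the rRNA share of gene reads in percent, the log2 difference of medians between short and long transcripts, and the mean log2(scaled value + 1) of acinar markers, ribosomal proteins, cytokines and NF-kB targets, and beta cell identity genes. All 6 GDM libraries had 8.55% rRNA reads or less, while lean libraries ranged from 1.84% to 39.0%, and ribosomal protein levels were 10.7 to 11.6 in GDM libraries against 9.69 to 10.4 in lean ones.

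Offspring of GDM dams were compared with offspring of lean dams first as an average over both weaning diets. Genes of beta cell identity and glucose sensing were lower in offspring of GDM dams. Nkx6-1, a transcription factor of mature beta cells (chromosome 14, 9516942 to 9523869, build rn5), fell 1.82-fold (log2 -0.87 ± 0.260 SE, adjusted p = 0.0480). Its values went from 639 ± 173 and 563 ± 96.1 in Lean-LF and Lean-HFS to 319 ± 167 and 378 ± 134 in GDM-LF and GDM-HFS (SD, n = 3). The vitamin D receptor gene Vdr (chromosome 7, 139536241 to 139585928) fell 2.60-fold (log2 -1.38 ± 0.295, adjusted p = 0.0158), and Ffar1, the fatty acid receptor that amplifies insulin secretion, fell 1.78-fold (log2 -0.83 ± 0.188, adjusted p = 0.0191). Neurod1 and Nkx2-2, transcription factors of islet cells, fell by 0.62 and 0.54 on the log2 scale. In this list 0 genes rose, 5 fell and 19 of 24 did not pass; adjusted over the list alone, 1 rose and 11 fell (camera adjusted p = 0.000643; adjusted p = 0.644 with an estimated correlation). The list did not pass with Rn45s as a covariate (median -0.10 against -0.39, camera adjusted p = 0.148) or without the K libraries, with GDM-LF 3 alone in GDM-LF (0.0820). Pdx1 (log2 -0.26, adjusted p = 0.325), Slc2a2, the glucose transporter (-0.63, 0.0796), and Ucn3 (-0.53, 0.0911) did not pass.

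Genes of insulin secretion and exocytosis were lower as well. Vamp2, a vesicle protein that acts in membrane fusion, fell by 1.03 ± 0.245 on the log2 scale (adjusted p = 0.0223). It stood at 420, 424, 202 and 215 in Lean-LF, Lean-HFS, GDM-LF and GDM-HFS. Rab3a, a GTPase of secretory vesicles, fell by 0.68. Of 25 members 0 rose, 6 fell and 19 did not pass. With p adjusted over the list alone, 11 fell (camera adjusted p = 2.5e-05; adjusted p = 0.644 with an estimated correlation). Ppy, the pancreatic polypeptide gene (chromosome 10, 89831063 to 89832358), rose 3.06-fold (log2 1.61 ± 0.394, adjusted p = 0.0238), from 2495 ± 487 and 9405 ± 7102 to 12500 ± 6413 and 18010 ± 9026. With Rbp4 (log2 0.99) it made 2 risen genes of 8 delta and PP cell markers, while 0 fell and 6 did not pass. Adjusted over the list alone, 3 rose (camera adjusted p = 0.0368; adjusted p = 0.644 with an estimated correlation). That call did not hold with the length trend removed (camera adjusted p = 0.178), without the K libraries (0.107), or without Lean-LF 3, Lean-HFS 3, GDM-LF 2 or GDM-HFS 3 (up to 0.120). Among 13 islet hormones and granule peptides 1 rose (Ppy), 1 fell (Scg3, log2 -0.84) and 11 did not pass; adjusted over the list alone, 2 rose and 1 fell (camera adjusted p = 0.509; adjusted p = 0.644 with an estimated correlation). Ins1 (log2 0.29 ± 1.86, adjusted p = 0.933), Ins2 (0.06, 0.978), Gcg (0.65, 0.386), Sst (0.57, 0.120) and Iapp (0.49, 0.199) did not pass. The wide SE of Ins1 came with the mean-variance trend at the highest values, and without that trend it was 0.134 (adjusted p = 0.176).

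Inflammatory genes were higher in offspring of GDM dams as an average over diets. The mean level of cytokines and NF-kB targets differed by 1.88 on LF and 0.19 on HFS diet (SE 0.517 each), and that of interferon response genes by 1.46 and 0.35 (SE 0.521). The chemokine gene Ccl2 (chromosome 10, 69047091 to 69048889) rose 5.66-fold (log2 2.50 ± 0.603, adjusted p = 0.0233), from 103 ± 51.7 and 187 ± 96.4 to 2608 ± 3234 and 461 ± 383. The chemokine and growth factor genes Cxcl2, Cxcl1 and Csf3 rose by 2.20, 2.36 and 2.19 on the log2 scale. Sod2, the mitochondrial superoxide dismutase and an NF-kB target, rose by 1.09 ± 0.209 (adjusted p = 0.0124). Of 24 cytokines and NF-kB targets 9 rose, 0 fell and 15 did not pass. With p adjusted over the list alone, 12 rose (camera adjusted p = 7.5e-06; adjusted p = 0.644 with an estimated correlation). Isg15, a ubiquitin-like protein induced by interferon, rose 4.59-fold (log2 2.20 ± 0.553, adjusted p = 0.0267), with Ifi27 (1.21), Psmb9 (1.12), Psmb8 (0.98) and Rtp4 (2.00) also risen. Of 28 interferon response genes 5 rose, 0 fell and 23 did not pass. Adjusted over the list alone, 12 rose (camera adjusted p = 7.5e-06; adjusted p = 0.644 with an estimated correlation). Ccl2 stood at 1100, 6321 and 404 and Isg15 at 38.0, 564 and 48.9 in GDM-LF 1, GDM-LF 2 and GDM-LF 3. The library highest for both, GDM-LF 2, also had the highest acinar level.

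Genes of ribosomes and of the respiratory chain were higher in offspring of GDM dams. Rps14 (chromosome 18, 55276797 to 55281581) rose 3.63-fold (log2 1.86 ± 0.285, adjusted p = 0.00966), from 1652 and 1958 to 6401 and 6855. Of 77 ribosomal protein genes, a list chosen after the data were seen, 68 rose, 0 fell and 9 did not pass. All 77 were higher, and 72 rose adjusted over the list alone. Cox7a2 (chromosome 8, 86753411 to 86757509) rose 2.25-fold (log2 1.17 ± 0.178), with Ndufa1 (1.29) and Ndufa2 (1.10) at the same adjusted p of 0.00966 and Atp5h at 0.69. Of 51 nuclear genes of oxidative phosphorylation 26 rose, 0 fell and 25 did not pass; adjusted over the list alone, 32 rose and 2 fell (camera adjusted p = 1.9e-10; adjusted p = 0.644 with an estimated correlation; fry adjusted p = 0.0288). Across all genes the fold change was lower for longer transcripts (Spearman rho -0.397 across genes, which are not independent replicates). Genes that rose had a median length of 1029 bases and genes that fell 3354. With the length trend removed, 28 ribosomal protein genes rose (median log2 0.42, against 1.01). Oxidative phosphorylation was left with 7 risen and 3 fallen genes and a camera adjusted p of 0.368. Atp5h turned to a log2 value of -0.04.

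Metabolic and stress genes changed in both directions. Lactate dehydrogenase A (Ldha), normally kept low in beta cells, rose 2.42-fold (log2 1.27 ± 0.231, adjusted p = 0.0122) and the mitochondrial protein gene Higd1a 3.54-fold (log2 1.82 ± 0.282, adjusted p = 0.00966). Hypoxia genes gave 6 risen and 0 fallen of 17 (7 risen adjusted over the list alone; camera adjusted p = 0.00705). With an estimated correlation the adjusted p was 0.696 for immediate early genes and 0.644 for hypoxia and each other list that follows here, so none passed by that test. Genes usually silent in mature beta cells gave 2 risen (Ldha, Hk2) and 1 fallen (Cat) of 19 (3 and 1 adjusted over the list alone; 0.0443). Immediate early genes, which tissue dissociation also induces, gave 4 risen and 0 fallen of 27 (4 adjusted over the list alone; 0.00979). Apoptosis and p53 targets gave 2 risen, Mdm2 and Gadd45b, and 0 fallen of 21 (2 adjusted over the list alone; 0.0366). Chac1 (log2 -0.93 ± 0.162, adjusted p = 0.0116), Sel1l, Atf6 and Syvn1, which act in endoplasmic reticulum stress and protein disposal, all fell. They were among 8 fallen and 0 risen of 30 genes of the unfolded protein response (9 fell and 2 rose adjusted over the list alone; 0.00705). Srebf1, a transcription factor that drives lipid synthesis, fell by 0.82 (adjusted p = 0.0204), with 4 fallen and 0 risen of 22 genes of fatty acid and triglyceride synthesis (4 adjusted over the list alone; 0.0117). Foxo1, Irs2, Igf2 and Igf1r fell by 0.93, 0.85, 0.65 and 0.80, with 0 risen of 21 genes of insulin and IGF signalling (6 fell and 1 rose adjusted over the list alone; 0.0381). Of 23 antioxidant genes 5 rose, Txn1 (0.98) and Prdx1 (0.74) among them, and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.192; fry adjusted p = 0.0288). Hypoxia genes stood at 0.0546 without GDM-LF 3 and immediate early genes at up to 0.217 without Lean-LF 3 or GDM-LF 2. The p53 targets stood at up to 0.122 without Lean-LF 3, Lean-HFS 1 or GDM-LF 2. Insulin and IGF signalling stood at up to 0.0924 without Lean-LF 2, Lean-HFS 2, Lean-HFS 3, GDM-LF 3 or GDM-HFS 2. Silent genes passed in only 5 of the 12 fits without 1 library (up to 0.154), the exceptions being those without Lean-LF 1, Lean-LF 3, Lean-HFS 1, Lean-HFS 2, GDM-LF 1, GDM-LF 2 or GDM-HFS 2. Removal of the length trend left lipid synthesis at 0.0885, p53 targets at 0.149 and insulin and IGF signalling at 0.105. With the acinar level as a covariate silent genes stood at 0.424, p53 targets at 0.378 and immediate early genes at 0.727. With Rn45s as a covariate lipid synthesis stood at 0.112, insulin and IGF signalling at 0.166, silent genes at 0.107 and p53 targets at 0.0505, the last 2 at medians of 0.30 each against 0.37 and 0.36. Without the K libraries, with GDM-LF 3 alone in GDM-LF, the unfolded protein response stood at 0.457, p53 targets at 0.234, silent genes at 0.618 and immediate early genes at 0.208.

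Markers of other cells also differed between offspring of GDM and of lean dams. Acinar genes had a median log2 difference of 1.08 (camera adjusted p = 0.000583; adjusted p = 0.696 with an estimated correlation), and only Try4, a trypsin gene, rose of 32 (log2 3.15 ± 0.759; 1 adjusted over the list alone). Prss1, the most abundant trypsin gene, stood at 8448 ± 4664, 20020 ± 21080, 37390 ± 54300 and 29400 ± 14850 in Lean-LF, Lean-HFS, GDM-LF and GDM-HFS. The acinar list did not pass without the K libraries (camera adjusted p = 0.371), where GDM-LF is 1 library, and its median was 0.37 without GDM-LF 2. Duct markers were higher, with Car2 risen of 15 (1 adjusted over the list alone; camera adjusted p = 0.0256; adjusted p = 0.657 with an estimated correlation). Erythrocyte markers were higher, with Hba-a1 risen of 9 (1 adjusted over the list alone; 0.0256; adjusted p = 0.644 with an estimated correlation). Neither passed without the K libraries (0.618 and 0.512). Duct markers did not pass without Lean-LF 3, Lean-HFS 2 or GDM-LF 2 (up to 0.102) and erythrocyte markers without GDM-LF 2 (0.0982). Endothelial markers were lower, with Eng and Kdr fallen by 0.75 and 0.87 of 17 (2 adjusted over the list alone; 0.0310; adjusted p = 0.696 with an estimated correlation). They did not pass without Lean-LF 3, Lean-HFS 3, GDM-LF 3 or GDM-HFS 1 (up to 0.161). Removal of the length trend ended the calls of endothelial (0.0869) and erythrocyte markers (0.105), and the acinar level as a covariate those of duct (0.493) and erythrocyte markers (0.298). Lists of alpha cell (camera adjusted p = 0.509), Reg family (0.173), macrophage (0.246), MHC class II (0.885), T and B lymphocyte (0.588), Schwann (0.885), stellate, fibroblast and matrix (0.885) and circadian clock genes (0.440) did not pass and held 0 changed genes by limma. In the fit without the K libraries macrophage genes turned to higher (0.0477) and stellate genes to lower (0.0130), and with Rn45s as a covariate stellate (0.000814) and erythrocyte genes (0.845) turned to lower. Stellate genes were also lower without GDM-LF 1 (0.0452). For MHC class II the median was 0.05, the mean -0.03 and the test pointed down. Dedifferentiation genes (Cck risen of 9; 0.173), glycolysis (2 risen of 20; 0.285) and adipocyte markers (Cidec risen of 7; 0.287) did not pass as lists either. Nor did fatty acid oxidation (Cpt2 fallen of 30; 0.776), cholesterol synthesis (Srebf2 fallen of 26; 0.246) and cell cycle genes (Mcm7 risen and Ccnd1 fallen of 28; 0.287).

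**Figure D2:**
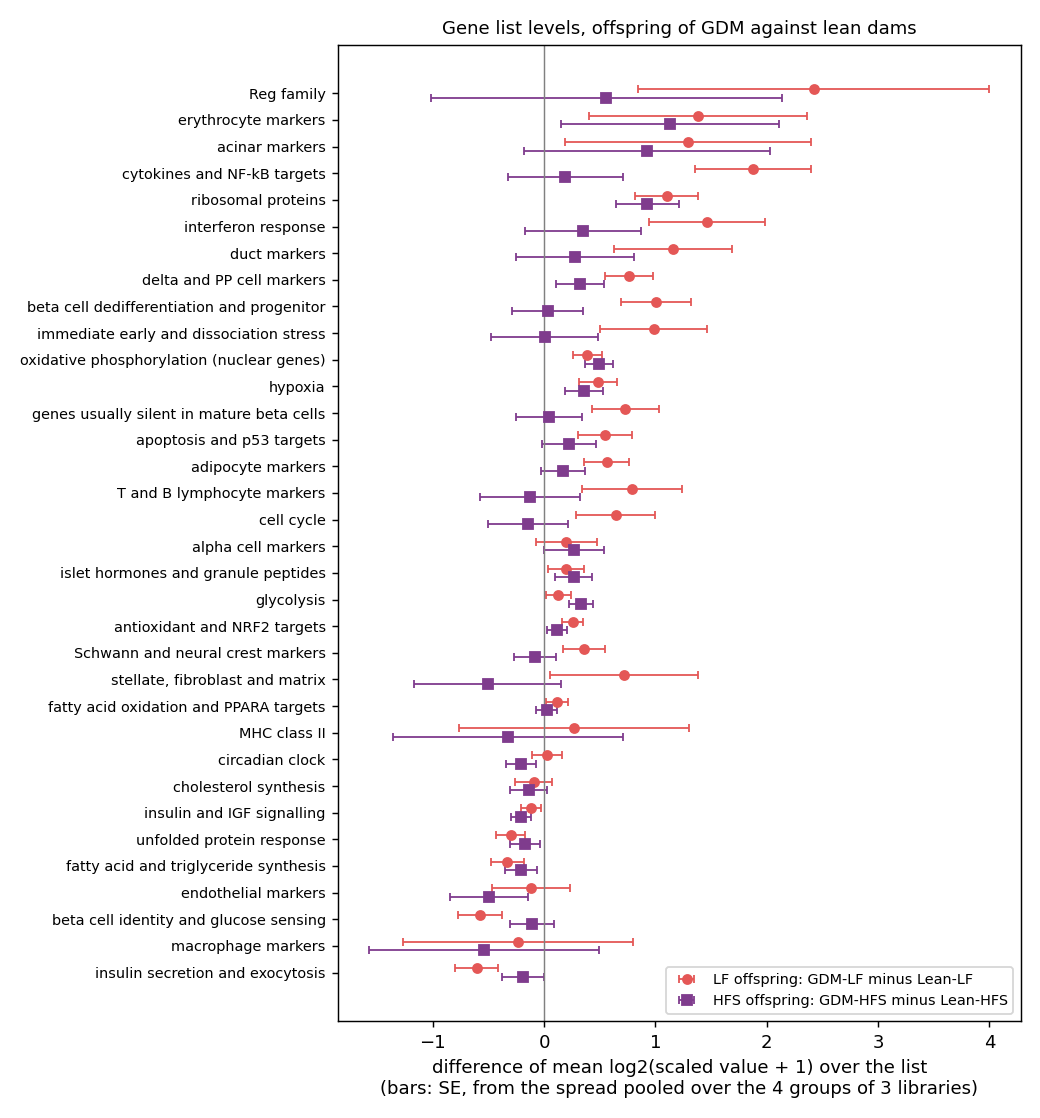
Difference of the mean log2(scaled value + 1) of each gene list between offspring of GDM and of lean dams, on LF diet (red circles, GDM-LF minus Lean-LF) and on HFS diet (purple squares, GDM-HFS minus Lean-HFS); bars are the SE with the spread pooled over the 4 groups of 3 libraries. Cytokines and NF-kB targets differed by 1.88 on LF and by 0.19 on HFS diet; on HFS diet the medians of beta cell identity and exocytosis genes, -0.13 and -0.20, were 0.09 and 0.02 with the deposited values without rescaling.

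By limma, GDM of the dam changed 1426 of 12339 genes averaged over diets, 756 up and 670 down, with 3816 genes at an unadjusted p under 0.05. Hspb6, a small heat shock protein (chromosome 1, 90162932 to 90165071), fell 3.22-fold (log2 -1.69 ± 0.299, adjusted p = 0.0119). Other large falls were Runx1t1 (log2 -1.92), the calcium channel gene Trpv6 (-1.66), Serpina6, Extl1, Dmp1, Reep6, Cox6a2, Samd5, Gucy2c (-1.42) and Astn1. Other large rises were Mis18a (2.73), Rn7sl1 (2.58), Polr2l (2.09), Rps19 (2.03) and the complement gene C3 (2.02). edgeR on recovered reads called 1526 genes (687 up and 839 down) and DESeq2 2277. The count was 342 with the acinar level as a covariate, 552 with the length trend removed (234 up and 318 down), 671 without the mean-variance trend and 2568 with library weights. A stronger simulated length trend alone (Spearman rho -0.76, real -0.40) gave 1409 calls, which cannot size the real effect. The deposited values without rescaling gave 429 up and 245 down. With that scaling the median log2 value of all genes was -0.35 for diet in offspring of lean dams, -0.17 for GDM on LF diet, 0.20 for GDM on HFS diet, -0.14 for diet averaged over dams and 0.42 for the interaction, where rescaling left -0.01 to 0.05. List medians moved with it, for beta cell identity on LF diet from -0.56 to -0.78. With Rn45s as a covariate, with the title letter as a covariate, or without the 3 K libraries, limma called 0 genes, with 434, 1867 and 2111 at an unadjusted p under 0.05. The K libraries hold no offspring of lean dams, so they give no value of their own, and the fit without them has GDM-LF 3 as its single GDM-LF library. Leaving out 1 library moved the count to 183 (without Lean-LF 2), 207 (Lean-LF 1), 369 (GDM-HFS 3), 395 (Lean-HFS 1), 784 (GDM-LF 2 or GDM-HFS 2), 2160 (GDM-LF 3) and 2471 (Lean-LF 3). Of the 84 named genes that passed, 16 passed whichever library was left out: Atp5h, Chac1, Cox7a2, Higd1a, Hspb6, Ifi27, Ldha, Ndufa1, Ndufa2, Prdx1, Rpl36a, Rpl37a, Rpl39, Rps14, Sod2 and Txn1. Nkx6-1 passed in 3 of the 12 fits without 1 library (adjusted p 0.0135 to 0.130), those without Lean-LF 3, GDM-LF 3 or GDM-HFS 1. Vdr and Ffar1 did not pass without Lean-LF 1, Lean-LF 2 or GDM-HFS 3 (up to 0.0578 and 0.0670), and Ccl2 not without any of these or Lean-HFS 1 (up to 0.0764). Ppy and Isg15 did not pass without these 4 libraries or GDM-HFS 2 (up to 0.0765 and 0.0757).

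**Figure D3:**
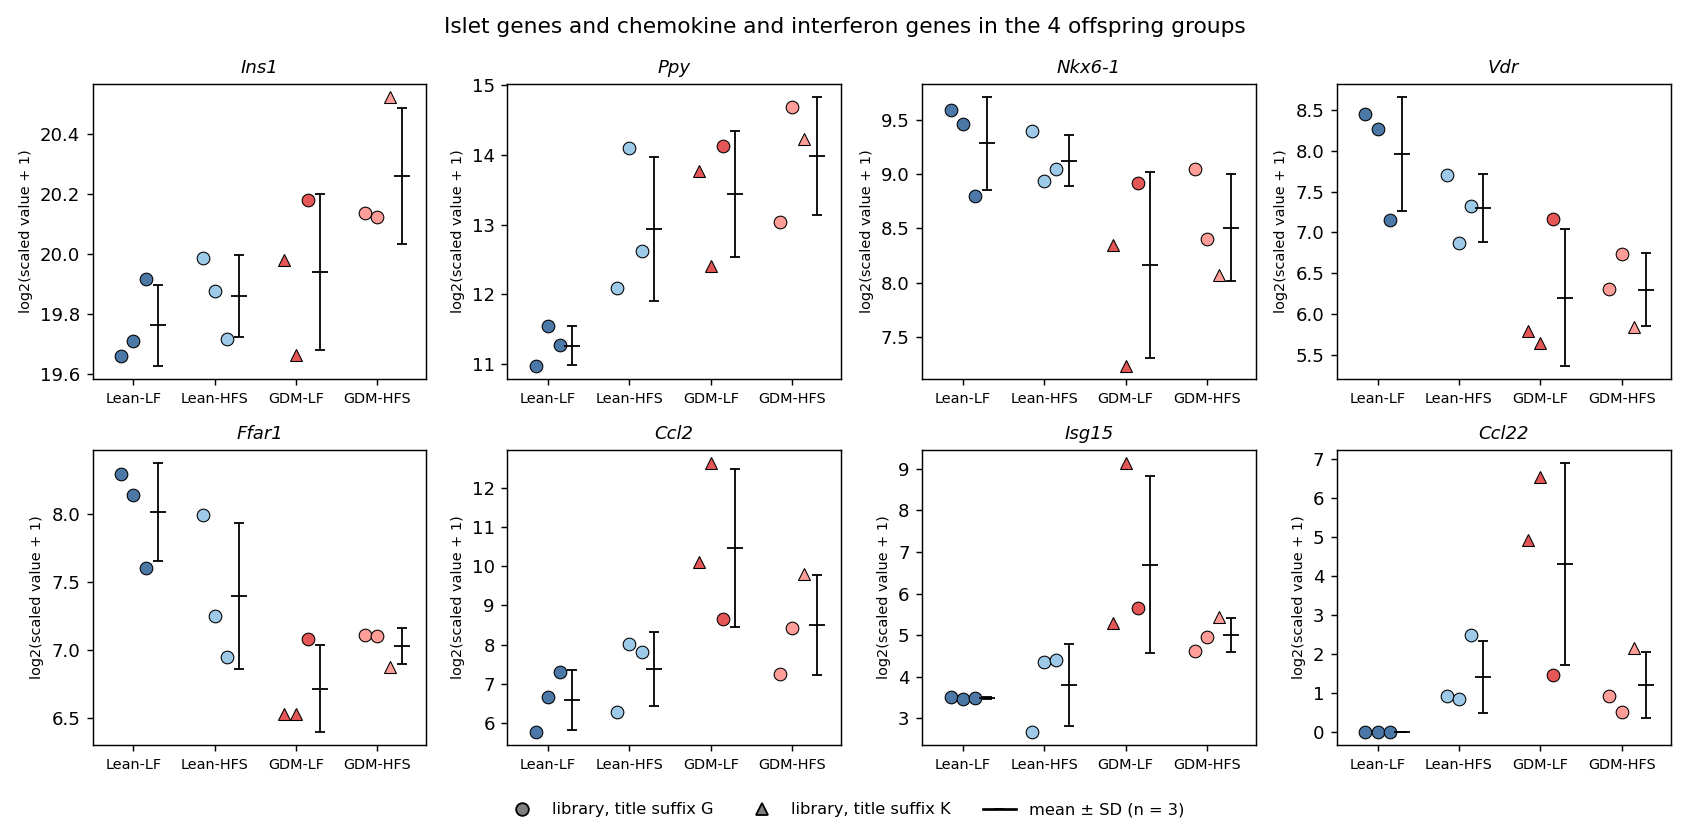
Values of Ins1, Ppy, Nkx6-1, Vdr, Ffar1, Ccl2, Isg15 and Ccl22 as log2(scaled value + 1) in each library (circle, title letter G; triangle, title letter K) with the mean ± SD of each group (n = 3). Ccl22 was at 0 in all 3 Lean-LF libraries and at 29.4, 91.2 and 1.75 in the GDM-LF libraries.

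In offspring weaned onto LF diet, GDM of the dam went with higher cytokine and interferon genes and lower genes of insulin secretion and beta cell identity, by a list test with a preset correlation. With an estimated correlation 0 of 33 lists passed (adjusted p = 0.478 or more). The chemokine gene Ccl22 (chromosome 19, 10668403 to 10675173) was at 0 in Lean-LF and at 40.8 ± 45.8 in GDM-LF, at least 47.0-fold higher against the floor of 3 reads per library, or 17.9-fold without GDM-LF 2. The GDM-LF libraries stood at 29.4, 91.2 and 1.75. Ccl2 rose by 3.89 ± 0.853 on the log2 scale, Slfn4 by 3.73 ± 0.704 (2.27 ± 1.97 to 38.4 ± 22.2), Cxcl2 by 3.73 ± 0.798 (12.6 ± 9.30 to 253 ± 310) and the interleukin gene Il1a by 3.70. Map1a, a microtubule protein of neurons and endocrine cells (chromosome 3, 119797486 to 119811427), fell by 1.71 ± 0.350 (847 ± 345 to 258 ± 104), the receptor gene Grin1 by 1.70 and the lysosomal glucosidase gene Gaa by 1.38. All of these had an adjusted p of 0.0477, the smallest reached. Other large rises were Csf3, Ppp1r17 (3.06), Wnt7a, S100a6 (2.71), Orm1, Tnfaip6 and Anxa13, and other large falls Myo16, Tenm4, Slc45a1, Slc29a4 (-1.49), Lrrn2, Lingo3, Sts, Lhfpl4 and Gabbr2.

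Of 24 cytokines and NF-kB targets 5 rose in GDM-LF against Lean-LF, 0 fell and 19 did not pass. With p adjusted over the list alone, 17 rose and 1 fell (median log2 1.82, camera adjusted p = 1.8e-09). Interferon response genes gave 1 risen (Ifi27, log2 1.32) of 28, with 16 risen adjusted over the list alone (3.4e-08), and Isg15 stood at 3.20 (adjusted p = 0.0519). Ffar1 fell by 1.30 ± 0.266 as the 1 fallen of 24 beta cell identity genes (8 fell adjusted over the list alone; 2.4e-06). Of 25 exocytosis genes 0 rose and 1 fell (16 fell adjusted over the list alone; 1.1e-07). Srebf1 fell by 1.18 as the 1 fallen of 22 lipid synthesis genes (2 fell adjusted over the list alone; 0.00849). Oxidative phosphorylation gave 1 risen gene (Cox7a2, 1.11) of 51 (21 rose and 2 fell adjusted over the list alone; 5.5e-06), and the direction turned with the length trend removed (camera adjusted p = 0.573). That removal also left dedifferentiation and lipid synthesis genes at 0.0503 each, p53 targets at 0.0566 and delta and PP cell genes at 0.1. The p53 targets also stood at 0.1 with the acinar level as a covariate and stellate genes at 0.0760 with Rn45s. Immediate early genes gave 2 risen (Ier3, Hspa1b) of 27 (6 adjusted over the list alone; 1.8e-05) and hypoxia 2 of 17 (4 rose and 1 fell adjusted over the list alone; 0.0138). The p53 targets gave 1 risen (Mdm2) of 21 (2 adjusted over the list alone; 0.0163) and silent genes 1 (Ldha, 1.60) of 19 (3 adjusted over the list alone; 0.00277). Among ribosomal proteins 25 of 77 rose. The unfolded protein response (0.00259; 9 fell adjusted over the list alone), dedifferentiation (0.0206), delta and PP cell (0.0221), acinar (0.00251), duct (0.00259), stellate and fibroblast (0.0221) and cell cycle lists (0.0221) passed with 0 changed genes over all genes tested. Antioxidant genes (2 risen; 0.251), circadian genes (Nr1d2 risen; 0.929; median -0.20, mean 0.03) and glycolysis (1 risen; 0.955; median -0.02, mean 0.13) did not pass as lists. Ppy (log2 2.18 ± 0.557, adjusted p = 0.0569), Slc2a2 (-1.11, 0.0644), Nkx6-1 (-1.12, 0.0855), Sst (0.81, 0.140), Pdx1 (-0.53, 0.180), and Ucn3 (-0.61, 0.182) did not pass. Nor did Iapp (0.56, 0.324), Gcg (0.21, 0.872), Ins1 (0.18, 0.974) and Ins2 (-0.01, 0.997).

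The limma count for GDM on LF diet was 195 genes, 105 up and 90 down, with 3278 at an unadjusted p under 0.05, against 194 by edgeR and 1681 by DESeq2. It was 0 without Lean-LF 1, Lean-LF 2, GDM-LF 1 or GDM-LF 2 (1897, 2194, 2868 and 2265 at an unadjusted p under 0.05). It came to 1726 without Lean-LF 3 and 1680 without GDM-LF 3. Under the deposited scaling it was 80 up and 406 down, and under quantile normalization 124 up and 157 down. It was also 0 with Rn45s, the acinar level or the title letter as a covariate (2560, 2551 and 1462 at an unadjusted p under 0.05). It was 0 as well with a pseudocount of 0.1, without the filter on low values, with the length trend removed, without the mean-variance trend or with only the compared groups (3213, 3462, 2911, 3133 and 2584 at an unadjusted p under 0.05). Without the K libraries GDM-LF is GDM-LF 3 alone, and without the libraries over 10% rRNA reads Lean-LF is Lean-LF 3 alone. Each lone library is assumed to vary like the other groups, and the count of 0 in these fits (974 and 319 at an unadjusted p under 0.05) says little about the letter or the rRNA. Stellate genes turned to lower without GDM-LF 1 (camera adjusted p = 0.609) and acinar genes without GDM-LF 2 (0.733; median -0.12, mean 0.03). Duct genes did not pass without GDM-LF 2 (0.0597) nor hypoxia without GDM-LF 3 (0.257). Cell cycle genes did not pass without Lean-LF 3 or GDM-LF 1 (up to 0.609). The p53 targets (up to 0.162) and dedifferentiation genes (up to 0.0930) did not pass without Lean-LF 3 or GDM-LF 2, nor delta and PP cell genes without Lean-LF 3 (0.117). Against Lean-LF, GDM-LF 3 alone had acinar (0.580), stellate (0.164) and cell cycle genes (0.626) turned to lower. The duct (0.765), silent (0.535), p53 (0.354) and dedifferentiation lists (0.680) and the unfolded protein response (0.732) did not pass in that comparison.

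In offspring weaned onto HFS diet, 1 gene passed. Anks1b, a scaffold protein of synapses (chromosome 7, 30603416 to 31774566), rose 2.96-fold (log2 1.57 ± 0.198, adjusted p = 0.0266), from 53.3 ± 5.09 in Lean-HFS to 162 ± 33.2 in GDM-HFS, beside 95.4 in Lean-LF and 141 in GDM-LF. The next genes, at an adjusted p of 0.182, had higher values in GDM-HFS. They were the mitochondrial genes Cox7c (log2 1.25; 843 against 2001), Ndufa12 (1.12), Atp5h (0.89), Ndufa2 (1.24), Tomm7 and Cox7a2 (1.23), the oxidative stress sensor Park7 (0.80) and Myl6b and Myl6, whose entries overlap (both 1.27). Of 51 oxidative phosphorylation genes 0 passed over all genes tested by limma and 27 rose adjusted over the list alone (median log2 0.51, camera adjusted p = 8.0e-15; adjusted p = 0.862 with an estimated correlation). Across all genes the fold change was again lower for longer transcripts (Spearman rho -0.383), and transcripts under 1000 bases had a median log2 of 0.41. Without the length trend all 6 called lists still passed (lowest camera adjusted p 0.0129). Of 77 ribosomal proteins 63 rose adjusted over the list alone and 0 over all genes tested. Endothelial (median log2 -0.59, camera adjusted p = 0.00628), acinar (0.88, 0.00980), hypoxia (0.36, 0.0151), stellate and fibroblast (-0.48, 0.0151) and glycolysis genes (0.25, 0.0378) passed as lists with 0 changed genes. Each had an adjusted p of 0.862 with an estimated correlation. Leaving out 1 library moved the medians to between -0.93 (without Lean-HFS 1) and -0.30 (Lean-HFS 3) for endothelial, 0.40 (Lean-HFS 2) and 1.66 (Lean-HFS 3) for acinar and -1.07 (Lean-HFS 2) and -0.17 (Lean-HFS 3) for stellate genes. Without GDM-HFS 3 they were 0.18 for hypoxia and 0.16 for glycolysis. Adjusted over the list alone, 1 hypoxia gene, 1 delta and PP cell gene and 1 interferon gene rose, 2 genes of the unfolded protein response fell, and 3 antioxidant genes rose and 1 fell. Cytokines and NF-kB targets included Sod2 at 0.63 and Birc3 at 0.55, neither past the threshold.

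For GDM on HFS diet, 1758 genes had an unadjusted p under 0.05, and edgeR called 1 gene and DESeq2 251. Anks1b did not pass without Lean-HFS 1, Lean-HFS 2, Lean-HFS 3, GDM-HFS 2 or GDM-HFS 3 (adjusted p up to 0.282), nor with the acinar level, the title letter or Rn45s as a covariate, without the K libraries or without the mean-variance trend (1706, 1296, 208, 1234 and 1658 genes at an unadjusted p under 0.05). Over all alternatives its adjusted p ran from 1.65e-08 to 1.00. Only the compared groups in the fit gave 104 genes and library weights 57. Endothelial genes did not pass without Lean-HFS 3 or GDM-HFS 1 (camera adjusted p up to 0.166), and acinar genes not without Lean-HFS 1, Lean-HFS 2 or GDM-HFS 3 (up to 0.281) or with Rn45s as a covariate (0.0969). Stellate genes did not pass without Lean-HFS 1, Lean-HFS 3 or GDM-HFS 3 (up to 0.166) and hypoxia not without Lean-HFS 2 or GDM-HFS 3 (up to 0.134). Glycolysis did not pass without Lean-LF 2, Lean-LF 3, Lean-HFS 2 or GDM-HFS 3 (up to 0.189), and without the K libraries, with 2 GDM-HFS libraries, neither glycolysis (0.131) nor hypoxia (0.119) passed. Gcg (log2 1.09, adjusted p = 0.498), Ppy (1.05, 0.414), Nkx6-1 (-0.62, 0.474), and Ucn3 (-0.45, 0.494) did not pass. Iapp (0.41, 0.624), Sst (0.33, 0.689), Slc2a2 (-0.15, 0.866), Ins1 (0.40, 0.959), Ins2 (0.14, 0.980) and Pdx1 (0.02, 0.982) did not pass. Across genes, the GDM effects on LF and HFS diet had a Pearson r of 0.441 and a Spearman rho of 0.471. The sign was the same for 68.2% of genes, or 55.4% without rescaling, and 8 of 100 pairs of relabelled groups gave a size as large; genes are not independent replicates.

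HFS feeding of offspring of lean dams changed 0 genes by limma, with 269 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2. That gene was Fam111a (log2 9.25 by DESeq2, adjusted p = 0.0366), named after its value was seen. The genes of lowest p, all at an adjusted p of 1.00, included the protocadherins Pcdhb6 (6.04 ± 1.70 in Lean-LF against 0.299 ± 0.518 in Lean-HFS; chromosome 18, 30123238 to 30126600) and Pcdhb2. Others were Anks1b (95.4 against 53.3), Plekhs1, Nrxn3, Grb14, Nacc2, Trpm5 (79.1 against 41.3) and Zfyve26. Among 21 apoptosis and p53 targets 1 rose adjusted over the list alone. Fixed genes had log2 values of 1.67 (Ppy), 0.90 (Sst), 0.25 (Ins2), 0.22 (Gcg), 0.16 (Iapp), 0.10 (Ins1), 0.01 (Ucn3), -0.16 (Nkx6-1), -0.21 (Pdx1) and -0.31 (Slc2a2), none past the threshold.

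As lists, 10 of 33 passed in offspring of lean dams, and 0 with an estimated correlation, where the adjusted p was 0.713 for oxidative phosphorylation, 0.794 for acinar and 0.635 for delta and PP cell genes. Higher were oxidative phosphorylation (median log2 0.22, camera adjusted p = 7.8e-10), acinar (0.96, 1.8e-06), delta and PP cell (0.57, 0.00272), Reg family (1.96, 0.00580), dedifferentiation (0.47, 0.00580), hormone (0.24, 0.0170) and cholesterol synthesis genes (0.13, 0.0417). Lower were exocytosis (-0.17, 0.000483), beta cell identity (-0.16, 0.00580) and insulin and IGF signalling genes (-0.17, 0.0417). Without rescaling of the deposited values the medians of oxidative phosphorylation, hormone and cholesterol genes were -0.14, -0.13 and -0.23, and those of acinar, delta and PP cell, dedifferentiation, exocytosis, beta cell identity and insulin and IGF signalling genes 0.60, 0.23, 0.11, -0.54, -0.52 and -0.53. With the acinar level as a covariate, beta cell identity (median -0.01, camera adjusted p = 0.573), dedifferentiation (0.12, 0.173), exocytosis (-0.06, 0.226), Reg family (0.85, 0.0554) and insulin and IGF signalling genes (-0.16, 0.0554) did not pass. Nor did hormone (median 0.23, camera adjusted p = 0.294), dedifferentiation (0.59, 0.0871), delta and PP cell (0.415, 0.0949), cholesterol (0.07, 0.645) and Reg family genes (1.95, 0.165) with Rn45s as a covariate. As the hormone, dedifferentiation and Reg family medians stayed near their size or above it, these lost calls do not speak for rRNA as the cause. Removal of the length trend left hormone genes at a median of 0.12 (0.130), oxidative phosphorylation at 0.05 (0.105) and insulin and IGF signalling at -0.16 (0.105). The median of oxidative phosphorylation was 0.15, 0.10 and 0.35 without Lean-LF 1, Lean-LF 2 and Lean-LF 3. Lean-HFS 3 had the highest acinar level of the lean dams' offspring (11.4). Without it the acinar (median 0.24, camera adjusted p = 0.387), exocytosis (-0.07, 0.160), beta cell identity (-0.02, 0.582), dedifferentiation (0.15, 0.152) and Reg family lists (1.07, 0.191) did not pass. Acinar genes had a median of 1.46 without Lean-HFS 2 and 0.62 without Lean-LF 1. Without Lean-HFS 1 the median was -0.30 for beta cell identity, -0.31 for exocytosis, 0.33 for delta and PP cell and -0.01 for cholesterol genes. Without Lean-LF 1 it was -0.04 for beta cell identity, 1.07 for Reg family, 0.25 for cholesterol and -0.11 for insulin and IGF signalling genes, which stood at -0.08 without Lean-LF 2. Without Lean-LF 3 it was 0.32 for delta and PP cell and -0.28 for exocytosis genes, and without Lean-HFS 2 it was 0.28 for cholesterol genes. Reg family genes also did not pass without Lean-LF 1, Lean-LF 3 or Lean-HFS 1 (up to 0.215), beta cell identity not without Lean-LF 1 (0.274), and dedifferentiation and delta and PP cell genes not without Lean-LF 3. Hormone genes did not pass without Lean-LF 3, Lean-HFS 1 or Lean-HFS 2 (up to 0.218), and cholesterol genes not without Lean-LF 2, Lean-LF 3, Lean-HFS 1 or GDM-LF 3 (up to 0.587, turned to lower, without Lean-HFS 1). Insulin and IGF signalling did not pass without Lean-LF 1, Lean-LF 2, Lean-HFS 1, Lean-HFS 2 or GDM-HFS 3 (up to 0.299).

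HFS feeding of offspring of GDM dams changed 0 genes by limma and 0 by edgeR, with 1188 at an unadjusted p under 0.05, and 33 by DESeq2 (6 up and 27 down). The genes of lowest p had an adjusted p of 0.470. Lcn2, an acute phase protein, stood at 1828 ± 1289 in GDM-LF against 268 ± 107 in GDM-HFS, and the superoxide dismutase gene Sod1 (chromosome 11, 33982764 to 33988340) at 2359 ± 80.5 against 4150 ± 176 (SD, n = 3). The others were Slfn4 (log2 -3.38), Orm1 (-3.01), Irf4 (-2.87), Steap4 (-2.60), Itm2a (-2.58), Ccnl1 (-1.21), Napepld (1.20 ± 0.229) and Creld1 (0.68). Leaving out GDM-LF 3 gave 40 genes (15 up and 25 down) by limma. Slc2a2 (log2 0.64, adjusted p = 0.527), Gcg (1.10, 0.601), Pdx1 (0.34, 0.644), Sst (0.41, 0.686), Ppy (0.54, 0.749), Nkx6-1 (0.34, 0.763), Ucn3 (0.18, 0.857), Ins2 (0.40, 0.953), Ins1 (0.32, 0.980) and Iapp (0.01, 0.993) did not pass.

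Cytokines and NF-kB targets were lower in GDM-HFS than in GDM-LF as a list (median log2 -1.49, camera adjusted p = 1.6e-14; 12 of 24 fell adjusted over the list alone; adjusted p = 0.550 with an estimated correlation, by which 0 lists passed). So were stellate and fibroblast (-1.14, 1.6e-09), interferon response (-0.72, 1.2e-08), immediate early (-0.87, 4.2e-08), silent (-0.69, 0.000327), endothelial (-0.45, 0.000972), cell cycle (0.00428) and duct genes (0.0197). Higher were oxidative phosphorylation (0.30, 1.6e-12), beta cell identity (0.31, 0.000478), exocytosis (0.30, 0.00323), hormone (0.0197) and acinar genes (0.0197); adjusted over the list alone, 1 dedifferentiation gene and 1 gene of insulin and IGF signalling fell and 1 antioxidant gene rose, in lists that did not pass. Beta cell identity had an adjusted p of 0.569 with an estimated correlation. Without GDM-LF 2, the lists that did not pass were interferon response (0.127), immediate early (0.208), beta cell identity (0.208), silent (0.0807), exocytosis (0.626), hormone (0.123) and duct genes (0.972; the median stayed at -0.03 while the test pointed up). Without the K libraries GDM-HFS 1 and GDM-HFS 2 stand against GDM-LF 3 alone, which is assumed to vary like the other groups. There exocytosis genes turned to lower (0.690) and duct (0.200) and cell cycle genes (0.236) to higher, and stellate (0.701), beta cell identity (0.768), silent (0.835), endothelial (0.489), hormone (0.701) and interferon genes (0.0804) did not pass. Stellate genes passed without GDM-LF 1 at a median of -0.28 (0.00565), and cytokines without GDM-LF 2 at -0.84 (1.7e-07). The interferon median was -1.24 without GDM-LF 1 and -0.17 without GDM-LF 2, where immediate early genes stood at -0.28 and silent genes at -0.34. For beta cell identity it was 0.19, 0.50 and 0.20 and for exocytosis 0.11, 0.49 and 0.18 without GDM-LF 2, GDM-LF 3 and GDM-HFS 1. Endothelial genes stood at -0.24 without GDM-HFS 1 and -0.75 without GDM-HFS 2. Removal of the length trend left hormone genes at 0.0927 (median 0.25 against 0.38) and acinar genes at 0.0657 (0.40 against 0.51). Rn45s as a covariate left acinar genes at 0.0803 (median 0.45 against 0.51). Cell cycle genes stood at 0.803 without GDM-LF 1, endothelial genes at 0.0969 without GDM-HFS 1, and hormone and duct genes did not pass without GDM-HFS 2. Acinar genes ranged from 1.0e-20 without GDM-LF 2 to 0.822, turned to lower, without GDM-LF 3, and did not pass without GDM-LF 1 or GDM-HFS 3 either.

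Averaged over dams, HFS diet changed 0 genes by limma and 0 by edgeR, with 611 at an unadjusted p under 0.05, and 2 by DESeq2, among them Fam111a (log2 8.49, adjusted p = 1.23e-05), named after its value was seen. The imprinted gene Mest (log2 0.98 ± 0.227) stood at 143, 220, 92.9 and 239 in Lean-LF, Lean-HFS, GDM-LF and GDM-HFS. With Orm1 (-1.66), Osgepl1 (-0.95), Lcn2 (-1.60), Sod1 (0.52), Cst6 (0.42), Igfbp5 (-1.21) and Dclk3 (0.79) it was among the genes of lowest p, at an adjusted p of 0.884. Ppy (1.11), Sst (0.66), Gcg (0.66), Ins2 (0.33), Ins1 (0.21), Slc2a2 (0.17), Nkx6-1 (0.09), Ucn3 (0.09), Iapp (0.09) and Pdx1 (0.07) did not pass. All 51 oxidative phosphorylation genes were higher on HFS (median log2 0.27, camera adjusted p = 6.5e-22; adjusted p = 0.429 with an estimated correlation, by which 0 lists passed) and all 24 cytokines and NF-kB targets lower (-0.61, 3.4e-10; 1 fell adjusted over the list alone). Acinar (0.80, 1.1e-06), hormone (0.29, 0.000547), delta and PP cell (0.0207; 3 rose adjusted over the list alone) and cholesterol genes (0.10, 0.0226; median -0.04 without rescaling) also passed as higher. Stellate (-0.61, 3.1e-06), interferon (-0.43, 1.3e-05), immediate early (0.000301), endothelial (0.000547) and silent genes (0.0226) passed as lower. Without GDM-LF 2 interferon (0.396) and immediate early genes (0.906) did not pass, nor stellate genes without GDM-LF 1 (0.0584; median -0.19). Without GDM-LF 2 the median was -0.27 for cytokines, which passed, and -0.06 for interferon genes. Acinar medians ran from 0.39 without GDM-LF 3 to 1.44 without GDM-LF 2, and the stellate median was -0.34 without Lean-HFS 2. With Rn45s as a covariate silent (0.121; median -0.19 against -0.25) and cholesterol genes (0.158; 0.08 against 0.10) did not pass. The cholesterol median was -0.01 without Lean-HFS 1. Endothelial genes did not pass without Lean-HFS 1 or GDM-HFS 1 (up to 0.0759), nor delta and PP cell genes without Lean-LF 3, GDM-LF 3 or GDM-HFS 3 (up to 0.109). Cholesterol genes did not pass without Lean-LF 2, Lean-LF 3, Lean-HFS 1 or GDM-HFS 1 (up to 0.677). Silent genes did not pass without Lean-LF 2, Lean-LF 3, Lean-HFS 1, Lean-HFS 2, GDM-LF 2 or GDM-HFS 1 (up to 0.396). With GDM-LF 3 as the single GDM-LF library, in the fit without the K libraries, silent genes turned to higher (0.747) and the stellate (0.939), interferon (0.324), endothelial (0.216) and hormone lists (0.0651) did not pass.

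Whether the effect of GDM differed between the weaning diets was tested as the interaction. By limma, edgeR and DESeq2 0 genes passed, with 730, 778 and 949 at an unadjusted p under 0.05. In simulated reads limma recovered 0% of 2-fold and 40% of 4-fold changes for the interaction, so a 2-fold change was not detectable with these libraries. The lowest p, at an adjusted p of 0.784, were those of Pcdhb6 (log2 3.68 ± 0.647), Pcdhb2 (3.06), Slc45a1 (1.88), Eif1 (-1.55), Ube2a (-1.26), Ptpn12 (-1.09), Rragc (-1.19), Colec12 (-2.72), Usp3 (-1.28) and Tnfaip2 (-3.00). Tnfaip2, which TNF induces, stood at 16.4, 22.8, 62.9 and 11.6 in Lean-LF, Lean-HFS, GDM-LF and GDM-HFS. Slc2a2 (0.96), Gcg (0.88), Pdx1 (0.55), Nkx6-1 (0.50), Ins1 (0.22), Ucn3 (0.16), Ins2 (0.15), Iapp (-0.14), Sst (-0.49) and Ppy (-1.13) did not pass. As lists, cytokines and NF-kB targets (median log2 -1.61, camera adjusted p = 9.8e-11; 1 fell adjusted over the list alone) and interferon response genes (-0.82, 1.7e-06) had a smaller GDM difference on HFS than on LF diet (adjusted p = 0.603 each with an estimated correlation). Beta cell identity (0.52, 4.2e-06) and exocytosis genes (0.50, 4.1e-06) had a less negative one (adjusted p = 0.603 each with an estimated correlation). Without rescaling the interaction medians were 0.97 for beta cell identity, 0.94 for exocytosis and -0.38 for interferon genes. With p adjusted over the list alone, 1 circadian gene fell, in a list that did not pass. In all 10 of 33 lists passed, and 0 with an estimated correlation; exocytosis genes had a median of 0.26 without GDM-LF 2 and 0.32 without GDM-HFS 1, and interferon genes -1.29 without GDM-LF 1 and -0.19 without GDM-LF 2. Interferon and dedifferentiation genes stood at 0.0697 without GDM-LF 2, duct genes at up to 0.313 without Lean-HFS 3 or GDM-LF 2 and cell cycle genes at 0.199 without GDM-LF 1. Without the K libraries, with GDM-LF 3 as the single GDM-LF library, the test turned up for duct (0.886) and cell cycle genes (0.949; median still -0.20), and stellate and dedifferentiation (0.659), silent (0.543) and exocytosis genes (0.079) did not pass. Across genes, the diet effects in offspring of lean and of GDM dams had a Pearson r of -0.07 and a Spearman rho of -0.06. The r turned to 0.11 without Lean-HFS 3 or GDM-LF 2 and 0.02 without Lean-LF 1, was -0.18 without GDM-LF 3 and -0.12 to -0.15 without Lean-LF 2, Lean-HFS 1 or Lean-HFS 2, and was -0.04 without GDM-HFS 2. It was -0.12 without rescaling and with the length trend removed. The sign was the same for 48.0% of genes, and 78 of 100 pairs of relabelled groups gave a size as large.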

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

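The counts under other splits of the libraries were planned. The tests of transcript length, Rn45s, title letter, acinar RNA, beta cell share and single libraries, and of handling by immediate early genes, were chosen only after the results were seen.

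By the interaction test of GDM and weaning diet 10 of 33 lists passed at the preset correlation of camera, and 0 with an estimated correlation (adjusted p = 0.603 for all 10). The median log2 difference on HFS less that on LF diet was higher for beta cell identity and glucose sensing (0.52) and insulin secretion and exocytosis (0.50). It was lower for cytokines and NF-kB targets (-1.61), stellate and fibroblast genes (-1.30), immediate early genes (-1.08), dedifferentiation genes (-0.97), interferon response (-0.82), duct markers (-0.75), cell cycle (-0.71) and genes usually silent in mature beta cells (-0.66). Single libraries moved several of these. Without GDM-LF 1 the stellate median was -0.40, cell cycle -0.27 and interferon -1.29; without GDM-LF 2 immediate early was -0.38, interferon -0.19, duct -0.30, dedifferentiation -0.51 and exocytosis 0.26. Duct was -1.43, dedifferentiation -1.63 and cell cycle -1.14 without GDM-LF 3, silent -0.40 and duct -0.42 without Lean-HFS 3, and exocytosis 0.32 without GDM-HFS 1. Without rescaling of the deposited values it was 0.97 for beta cell identity, 0.94 for exocytosis, -0.65 for immediate early, -0.86 for stellate, -0.56 for dedifferentiation, -0.38 for interferon, -0.46 for duct, -0.33 for cell cycle and -0.23 for silent genes. The camera adjusted p ran from 9.8e-11 for cytokines to 0.00926 for dedifferentiation genes. Of 100 splits of the libraries 73 gave at least as many lists, with up to 23 in the others, so chance cannot be excluded for this number of lists. For genes the interaction had 0 calls by limma (730 at an unadjusted p under 0.05; 0 by edgeR and DESeq2), all 100 splits gave as many, and the highest other gave 8.

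Rn28s, an rRNA entry, took 3.94% of gene reads on average in offspring of GDM dams, above the highest library from a lean dam (1.80%). Group means were 1.21 ± 0.818% in Lean-LF, 0.693 ± 0.701% in Lean-HFS, 5.69 ± 3.02% in GDM-LF and 2.20 ± 0.817% in GDM-HFS (SD, n = 3; exact permutation p = 0.01 between dams). The 45S precursor Rn45s went the other way, with log2 values of 17.87, 21.01, 16.52 and 15.12. No explanation was tested for this pair.

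The first pattern weighed is that ribosomal protein genes were higher in offspring of GDM dams, by a median log2 of 1.01. Lists matched on length and mean value had medians of 0.443 to 0.739, which argues against a library-wide length trend as the whole cause, although the match was imperfect (median lengths 595 against 694 bases, median values 1997 against 1367). With the Rn45s value as a covariate the difference of the list's mean was 0.57 ± 0.223, against 1.01 ± 0.200 before. This argues against the Rn45s level as the whole cause, though it may account for part. Rn45s took only 1.00% of gene reads in GDM-LF 1, where all rRNA took 8.55%, so the rRNA share itself was not tested. Without the K libraries, which leaves GDM-LF 3 alone in GDM-LF, the difference was 0.73 ± 0.204 (exact permutation p = 0.0250, the smallest that 40 relabellings can give), which argues against these 3 libraries as the whole cause. An effect of GDM in the dam or of the dam's diet stays open, with litter and sex not given in the labels used here.

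The second pattern is that beta cell identity genes were lower in offspring of GDM dams, by a median log2 of -0.39. Matched lists had medians of -0.18 to 0.14, which argues against a length trend as the whole cause. A lower share of beta cells would lower Ins1, Ins2 and Iapp as well, whose mean was higher by 0.28 ± 0.0987 (SE) against -0.34 ± 0.139 for the list; but these transcripts are short, and with the length trend removed the differences were -0.45 ± 0.155 and -0.38 ± 0.144, which are -0.0735 ± 0.0623 apart. Acinar less endothelial markers differed by 1.41 ± 0.764, but other cells need not rise alike. A lower share cannot be told from lower expression per cell, which whole islets cannot test. With Rn45s as a covariate the median of the list was -0.10 against -0.39 (camera adjusted p = 0.148). The difference was thus much smaller in that fit, and rRNA content stays open as a cause. The list passed with the acinar covariate but not without the K libraries, with GDM-LF 3 alone in GDM-LF. Over alternatives the camera adjusted p ranged from 5.9e-05 to 0.644.

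The third pattern is that cytokines and NF-kB targets were higher in GDM-LF than in Lean-LF, with a difference of 1.88 ± 0.517 in the list's mean log2 level. Without GDM-LF 2 it was 1.31 ± 0.386, with the acinar level as a covariate 1.34 ± 0.286, and with the title letter as a covariate 1.49 ± 0.629. Immediate early genes, which handling also induces, stood at 8.25 in GDM-LF 2, the library highest in cytokines, and at 5.86 to 6.45 in the 11 others; with their level as a covariate the difference was 0.997 ± 0.376. Each was tested alone. The values without GDM-LF 2 and with the acinar level argue against that library or acinar RNA as the whole cause. Each could still account for part of the difference. The immediate early level mainly sets GDM-LF 2 apart, so that fit says little about handling beyond that library. The letter K is on no lean library, so the fit with the letter cannot fully tell it from GDM. Handling, the title letter, GDM of the dam and litter stay open.

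The oxidative phosphorylation genes had a median log2 of 0.43 in offspring of GDM dams, inside the 0.252 to 0.540 of lists matched on length and mean value.

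Other splits of the libraries bear on each count of genes. For GDM averaged over diets the real split gave 1426 genes and was the 1 split of the 100 drawn to reach that number. The highest other drawn gave 472, by exchanging Lean-LF 3 with GDM-LF 3. This argues against a chance split for that count. It cannot tell GDM from other differences that go with the dams' label, such as the length measure or the rRNA share. For its 17 lists, 18 of 100 splits gave as many (highest other 20), and chance is not excluded. For diet averaged over dams all 100 splits gave at least the 0 genes of the real split (611 genes at an unadjusted p under 0.05 by limma, 0 by edgeR, 2 by DESeq2). Calls were made in 3 of the 100, with 49 in the highest other, and no structure among the libraries was tested for. At least its 11 lists were reached by 64 of 100 (highest other 23). The 10 splits of 3 against 3 libraries are too few for a share under 0.05. For GDM on LF diet the real split gave 195 genes and 17 lists and the highest other 0 and 16, for GDM on HFS diet 1 and 6 against 1 and 18, for diet in offspring of lean dams 0 and 10 against 0 and 20, and for diet in offspring of GDM dams 0 and 13 against 2 and 20. As many were reached, the real split included, by 1 and 1, 2 and 8, 10 and 3, and 10 and 7 of the 10 splits.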

How the results depend on the processing

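Tests with edgeR, DESeq2, Rn45s as a covariate, the length trend removed, no mean-variance trend, without the K libraries or those over 10% rRNA were chosen after the data were seen; the others were planned. Fits without libraries or with only the compared groups rest on fewer libraries; for the other changes the cause was not tested. Without the K libraries GDM-LF is GDM-LF 3 alone, and without those over 10% rRNA Lean-LF is Lean-LF 3 alone. Each is assumed to vary like the other groups, so lost calls and turned directions there say little about the letter or the rRNA.

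For GDM averaged over diets, the 1426 genes became 674 with the deposited values, 2568 with library weights, 342 with the acinar covariate, 552 with the length trend removed, 671 without the mean-variance trend and 2277 by DESeq2. The count was 0 by limma with the title letter or Rn45s as a covariate and without the K libraries (1867, 434 and 2111 at an unadjusted p under 0.05). A pseudocount of 0.1, no filter, a minimum of 5, quantile normalization and edgeR gave 1371, 1073, 1506, 1393 and 1526. Leaving out 1 library gave 183 (without Lean-LF 2) to 2471 (without Lean-LF 3). Of the 1426 genes, 672 were called in the same direction with the deposited values, 1277 after quantile normalization, 1313 by edgeR and 1413 by DESeq2. Among 84 named genes that passed, direction was kept in all fits without 1 library, and over the other alternatives only Atp5h, GDM against lean dams, averaged over diets, changed sign, to -0.0361 with the length trend removed.

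For GDM on LF diet, the 195 genes became 486 with the deposited values, 1768 with library weights and 1681 by DESeq2. The limma count was 0 with a pseudocount of 0.1, no filter, the acinar level, title letter or Rn45s as a covariate, the length trend removed, without the K libraries, without the mean-variance trend, without libraries over 10% rRNA and with only the compared groups. At an unadjusted p under 0.05 these had 3213, 3462, 2551, 1462, 2560, 2911, 974, 3133, 319 and 2584 genes. Leaving out 1 library gave 0 to 1726. For GDM on HFS diet, the 1 gene became 2 with the deposited values (Anks1b and Mir1843b, the latter named after its value was seen), 57 with library weights, 104 with only the compared groups and 251 by DESeq2. It became 0 by limma with the acinar level, title letter or Rn45s as a covariate, without the K libraries and without the mean-variance trend (1706, 1296, 208, 1234 and 1658 at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 1.

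For diet, DESeq2 called 1 gene in offspring of lean dams, 33 in offspring of GDM dams and 2 averaged over dams, against 0 by limma (269, 1188 and 611 at an unadjusted p under 0.05) and 0 by edgeR. Leaving out 1 library gave 0 to 40 genes in offspring of GDM dams, the highest without GDM-LF 3.

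The replicate numbers did not pair the libraries: 5 of 18 same-numbered pairs correlated above 0.1, and 4 of 12 libraries correlated best with their own number. With the replicate number as a block, GDM on LF diet gave 0 genes by limma (3147 at an unadjusted p under 0.05), GDM on HFS diet 2 and GDM averaged over diets 1140.

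Of 231 list tests 84 passed with camera at its preset correlation, 0 with an estimated correlation and 2 with fry (oxidative phosphorylation and antioxidant genes, GDM averaged over diets), and 70 to 98 passed with 1 library left out. For GDM averaged over diets, the list stellate, fibroblast and matrix (0.885) turned from higher to lower, with a camera adjusted p of 0.000814 with Rn45s as a covariate, 0.0130 without the K libraries and 0.0452 without GDM-LF 1 (up to 0.947 with 1 library left out). Erythrocyte genes turned to lower with Rn45s as a covariate (0.845), and macrophage genes from lower to higher without the K libraries (0.0477). Oxidative phosphorylation on LF diet turned to lower with the length trend removed (0.573). In the fit without the K libraries the acinar (0.580), stellate (0.164) and cell cycle lists (0.626) turned to lower for GDM on LF diet. For diet in offspring of GDM dams exocytosis genes turned to lower (0.690) and duct (0.200) and cell cycle genes (0.236) to higher. Silent genes turned to higher (0.747) for diet averaged over dams, as did the test of duct (0.886) and cell cycle genes (0.949) for the interaction. Over fits without 1 library, cholesterol genes in offspring of lean dams ranged from 0.000261 to 0.587. In offspring of GDM dams, diet gave acinar genes 1.0e-20 to 0.822 and duct genes 0.000182 to 0.972. On LF diet, GDM gave acinar genes 5.3e-06 to 0.733 and stellate genes 0.000307 to 0.609. At the upper end of each of these 5 ranges the direction had turned. The acinar list has no value with its own level as a covariate.

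Depth, at 11469290 to 27492858 reads over genes per library, limits low genes, for which 1 unit is 1.96 to 5.02 reads.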

Other observations

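The tests of list levels per library by exact permutation, ribosomal proteins included, were all chosen only after the results were seen.

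As the mean log2 level of each list in each library, oxidative phosphorylation and hypoxia genes were higher in offspring of GDM dams by 0.44 and 0.42, at the smallest p the 400 relabellings allow (two-sided exact permutation p = 0.00500 each). Interferon response genes differed by 0.91 (p = 0.01 by exact permutation), delta and PP cell genes by 0.54 and exocytosis genes by -0.40 (both 0.0150), cytokines by 1.03 (0.0400) and beta cell identity genes by -0.34 (0.0600). After adjustment over the lists the lowest p was 0.0825, so none passed. Hormone genes were the ones of lowest p for weaning diet, at 0.37 higher on HFS diet (exact permutation p = 0.01, adjusted 0.330). Ribosomal proteins differed by 1.01 (exact permutation p = 0.00500).

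Abundant genes of other pancreatic cells varied between groups and within GDM-LF. Of the 3 most abundant of each list, the endothelial gene Eng and the adipocyte gene Cidec passed for GDM averaged over diets (log2 -0.75, adjusted p = 0.04145, and 0.76, 0.0407) and the others did not. Without 1 library Eng passed in 3 and Cidec in 5 of 12 fits (adjusted p up to 0.120). Eng stood at 210 ± 46.1, 184 ± 62.3, 140 ± 36.0 and 99.1 ± 41.8 and Cidec at 142 ± 31.8, 152 ± 49.7, 283 ± 101.4 and 224 ± 71.4 in Lean-LF, Lean-HFS, GDM-LF and GDM-HFS (SD, n = 3). The matrix gene Col3a1 stood at 364 ± 264, 391 ± 296, 1631 ± 2362 and 224 ± 55.4 in the same order, and the globin gene Hbb at 331 ± 319, 272 ± 281, 1956 ± 2630 and 673 ± 183. Reg3b, an antimicrobial lectin, stood at 1258 ± 1328, 4560 ± 4593, 8207 ± 10950 and 5374 ± 5110. The amylase gene Amy2a3 stood at 5357 ± 1863, 12200 ± 12540, 48250 ± 68800 and 16090 ± 2798. Lpl, which encodes lipoprotein lipase, stood at 136 ± 57.3, 147 ± 15.3, 312 ± 335 and 258 ± 160. The endothelial gene Pecam1 stood at 170 ± 37.4, 179 ± 94.3, 153 ± 45.4 and 100.4 ± 53.6.

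The first principal component of the tested genes took 35.3% of their variance and the next 15.2%.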
